A study of Danio rerio with 15 samples.

How the data were processed

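Total RNA of caudal fin regions of AB wild-type zebrafish was sequenced at 3 positions, proximal, middle and distal, with 5 biological replicates each. Per the labels, each replicate is a pool of fin regions of 2 male and 2 female fish, the RNA was extracted with TRIzol and depleted of ribosomal RNA, and libraries were read as 50 bp pairs. The submitters' processing notes name TopHat2 2.0.13, HTSeq and DESeq and the GRCz10 genome, without the role or order of each tool. The gene annotation, the strand setting and the filters are not given in the sources used here.

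The authors deposited 3 tables of pairwise comparisons and 1 table of monotonic genes. The signal columns of the authors' pairwise tables hold, per the file headers, 1 value per position; their values are the mean over 5 libraries of read counts divided by a size factor per library, normalized within the pair. The signal columns of the authors' monotonic table are headed rpm, but a gene there reaches 2613310, so they are not in that unit; they are mean counts normalized over the 3 positions together. The deposited fold is the ratio of the means, with 0.001 added to both where 1 is 0, which was recomputed for 112 genes of the distal and proximal table, 21 of the middle and proximal table and 54 of the distal and middle table. The deposited log2 values are the log2 of that fold, and those of the monotonic table are copies of the pairwise ones. The p-value columns hold the authors' DESeq p-value and a p-value adjusted by Benjamini-Hochberg over the table, which was recomputed within 1e-06 for every gene. The score of the authors' monotonic table equals the sum over both steps of the log2 fold change times the negative log10 of the p-value, within 1e-06 for all 1144 genes. The pairwise tables hold 23404 genes (distal and proximal), 23556 (middle and proximal) and 23232 (distal and middle), each with a sum of means above 2, and 23926 gene IDs in all. Symbols came from the tables for 21221 IDs and from the reference list of names for 1370.

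Values per library were recovered from the means. A mean printed with 15 digits is a sum of 5 whole counts, each divided by its own size factor, and the size factors were read from genes with few reads. Lattice reduction then gave the 5 counts. Of 23495 genes with all 15 libraries, 23350 had a single solution and 145, all of high counts, did not. The counts were checked on means that had not been used, those of the monotonic table: 565, 567 and 559 genes of the proximal, middle and distal columns all lay within 1e-13 of the value. In simulated data every gene with a single solution, 23248, 23222 and 23211 for the 3 positions, had all its counts right. Library numbers follow the size factor within a position and are not the replicate numbers of the labels. Where a gene without a single solution is named, it is given with the authors' values alone and no SD.

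The test of each comparison, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, with an edgeR test in case counts per library were given and the authors' statistics otherwise. The tables give means, so a gene was called where the authors' adjusted p was under 0.05, and the sign of the fold gave its direction. Samples were grouped by position as labelled, and no sample was left out. The comparisons were distal against proximal, middle against proximal and distal against middle. A gene was monotonic where its 3 means were in order and it was called between the ends. As alternatives chosen after seeing the data, the recovered counts were fitted with limma 3.58.1 (voom, 1 fit of 15 libraries, the size factors read from the means, genes with at least 10 reads in at least 5 libraries). Further fits used no filter, totals of uniquely solved genes as scale, positions scaled to equal totals of all genes, only the positions compared, or all libraries but 1. All these fits, and the list tests built on them, kept the 145 genes without a single solution. Each entered with 1 of its possible solutions, so its spread between libraries is not known there. Counts were also simulated with 200 changed genes, all with a mean of at least 20, and libraries drawn independently. There the limma fit of the distal and proximal fin called 59.7%, 85.1% and 98.5% of genes changed 1.5, 2 and 4-fold, with 11 unchanged genes called of 18821 tested. For the middle and proximal fin it called 71.6%, 83.6% and 95.5%, and for the distal and middle fin 61.2%, 88.1% and 98.5%. Unchanged genes called numbered 5 and 13 in these 2 pairs. The data hold far more calls and libraries that deviate together, so these rates need not hold for them.

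The 29 gene lists covered HOX genes, appendage patterning transcription factors, the retinoic acid, FGF, Wnt, Hedgehog and BMP and TGF-beta pathways, bioelectric and fin size genes, osteoblast and bone matrix, fin ray joint and distal ray genes, cell cycle, immediate early and stress response, glycolysis, mitochondrial respiration, and amino acid and one-carbon metabolism. The others were markers of osteoclasts, cartilage, skeletal muscle, nerve and Schwann cells, erythrocytes, leukocytes, melanophores, iridophores, xanthophores, epidermis, ionocytes and mucous cells, endothelium, vascular smooth muscle and fibroblasts, and adipocytes. Of 1355 listed genes 1197 were matched by symbol. Called members were compared with all other tested genes by two-sided Fisher's exact tests, adjusted over lists and directions within a comparison. The lists were also tested with camera of limma, with a preset and an estimated correlation. Camera asks whether a list as a whole is shifted in a direction. It does not test for too few calls in a direction, nor for calls over-represented in both directions. Each adjusted p given with an estimated correlation is that of camera. With shuffled gene labels 4 of 3480 such Fisher tests passed the threshold.

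Named genes have an adjusted p under 0.05 and a symbol that is not provisional. They include the 10 largest and 10 smallest fold changes of the distal and proximal fin and 5 and 5 of each other pair. For these the mean is at least 20. With no minimum mean, they also include up to 4 called members per list and 5 genes per direction that the authors list as monotonic. Any called HOX or appendage gene may be named too. Members that were not called are named only as examples of high expression. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, mpmath 1.4.1 and matplotlib 3.10.9, and R 4.3.3.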

Results

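RNA was sequenced from the caudal fin of wild-type zebrafish of the AB strain at 3 positions along the proximodistal axis, which runs from the fin base to the fin tip. Each of the 15 libraries came from a pool of fin regions of 4 fish, 2 male and 2 female per the labels, with 5 libraries per position. Ribosomal RNA was depleted from total RNA. The title of the series places the work in the study of positional memory, the capacity of fin cells to retain where along the axis they lie, and the comparisons ask which transcripts differ between positions. The authors' deposited tables give 1 mean per gene and position, and the 5 normalized counts behind each mean were recovered from its digits. Levels are given throughout as the mean ± SD of these normalized counts (n = 5 libraries per position), and folds beside them are ratios of these means.

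Summed over all genes, a proximal library held 18525728 normalized counts on average, a middle library 17881283 and a distal library 17689454. The 145 genes whose 5 counts could not be solved uniquely include the most abundant transcripts. Over the remaining genes the libraries held from 8265716 to 11118932 reads. These genes made up 51.6% of the normalized counts proximally, 54.4% in the middle and 57.1% distally. The most abundant feature, ENSDARG00000080337, which has no symbol in the sources used here, took 14.1%, 10.9% and 8.85% of the counts from proximal to distal. The next, the 7SL RNA gene *rn7sl1*, took 7.22%, 5.83% and 4.66%; both were singled out after their values were seen. A floor of 3 reads over the 5 libraries of a position equals 0.576 normalized counts proximally, 0.567 in the middle and 0.653 distally, and covers counting error only.

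In a principal component analysis the 3 positions formed separate clusters. The first component held 56.5% of the variance and ran from −52.6 to −44.5 in the proximal, −24.6 to −17.0 in the middle and 60.0 to 74.1 in the distal libraries. The second held 8.90% and separated the middle libraries, at −29.3 to −25.1, from the proximal ones, at 16.8 to 25.02. The labels name no sequencing batch.

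**Figure D1:**
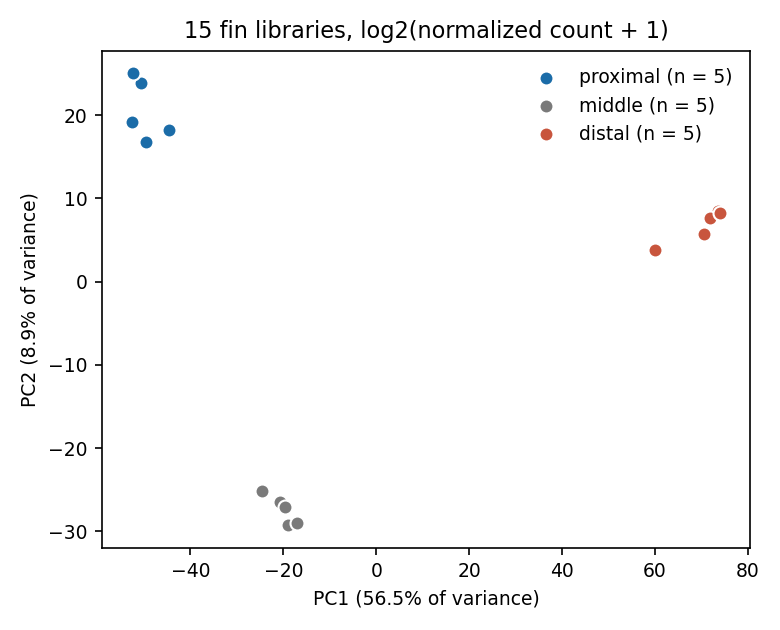
Scores of the 15 fin libraries on the first and second principal components of log2(normalized count + 1), in arbitrary units, coloured by position with 5 libraries each. The axis titles give the percent of variance, and the distal libraries lie at 60.0 to 74.1 on the first component while all other libraries lie below 0.

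Genes that differed between the distal and the proximal fin include genes of actinotrichia, signalling, patterning, pigment cells and mucous cells. The actinodin gene *and1* (ENSDARG00000088514), which encodes a structural protein of the actinotrichia fibrils at ray tips, stood at 6.72 ± 3.44 normalized counts proximally and 1960.0 ± 391 distally, 292-fold higher. The signalling genes *wnt5a* (ENSDARG00000104973) and *bmp4* (ENSDARG00000019995) were 14.6-fold and 7.05-fold higher distally, from 84.6 ± 15.1 to 1235 ± 91.7 and from 123 ± 6.97 to 871 ± 88.5. In the other direction, the Wnt-binding gene *sfrp2* (ENSDARG00000070050) fell from 1005 ± 91.3 to 34.6 ± 13.2, 29.1-fold lower, and the chondrogenic transcription factor gene *sox9a* (ENSDARG00000003293) fell from 1297 ± 109 to 169 ± 36.6. The secreted mucin gene *muc5.2* (ENSDARG00000058556) was 116-fold lower distally in the authors' deposited table, with an adjusted p listed as 0.

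Of 23404 genes in the authors' deposited table for this pair, 8415 were called at an adjusted p under 0.05, 4181 higher distally and 4234 lower. Among the 10 largest rises of genes with a mean of at least 20 over both positions, *and2*, another actinodin gene, had no read in any proximal library and 169 ± 54.0 normalized counts distally, at least 293-fold higher. The zinc finger gene *zic2b* stood at 0.778 ± 1.27 proximally and 47.1 ± 11.1 distally. The nociceptin precursor gene *pnocb* stood at 0.758 ± 1.04 and 42.8 ± 8.50, the endothelin receptor gene *ednrbb* at 3.65 ± 2.51 and 158 ± 27.0, and the BMP and Wnt antagonist gene *sostdc1b* at 1.15 ± 1.74 and 43.9 ± 7.57. The chemokine gene *cxl34c* was 37.9-fold and the serotonin receptor gene *htr2cl2* 37.7-fold higher distally. The other 2 of the 10 are both named *otud4*, with 2471 ± 2657 and 1006 ± 1672 normalized counts distally, an SD above the mean in each case. Reads of these 2 genes came from 3 of the 5 distal libraries almost alone, and both failed the count minimum of the limma fit. In the authors' deposited table adjusted p over these genes ran from 6.20e-101 for *and1* to 0.00596 for *otud4* ENSDARG00000087337.

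Among the 10 largest falls of such genes, 4 genes had no read in any distal library. The LIM homeodomain gene *lmx1bb* stood at 135 ± 38.5 proximally and was at least 207-fold lower distally. The ion channel accessory gene *fam155a*, the pyruvate carboxylase gene *pcxb* and the astacin metalloprotease gene *c6ast1* stood at 73.8 ± 12.1, 42.9 ± 9.02 and 43.4 ± 33.9 proximally. They were at least 113-fold, 65.7-fold and 66.5-fold lower distally. Without proximal library 2 the bound of *c6ast1* was 47.4-fold. The fatty acid binding protein gene *fabp1b.2* fell from 2981 ± 1619.8 to 1.96 ± 1.78, *vmo1a* from 254 ± 14.4 to 3.26 ± 1.796, and *galnt8b.2*, whose product starts mucin-type glycan chains, from 63.4 ± 18.6 to 0.189 ± 0.423. The secretory calcium-binding phosphoprotein gene *scpp7* stood at 247 ± 280.4 and 0.860 ± 1.39 and the papilin gene *paplnb* at 205 ± 158 and 1.51 ± 0.974; for *scpp7* the proximal SD exceeded the mean. In the authors' deposited table adjusted p over these 9 genes ran from 9.93e-129 for *vmo1a* to 0.000856 for *scpp7*.

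Patterning transcription factors of paired appendages and fins moved both ways, more of them higher distally. The fixed list had 26 of 59 measured members higher and 15 lower (26 and 18 adjusted over the list alone), with Fisher's exact test at adjusted p = 2.02e-05 for higher and 0.252 for lower calls. As a whole the list showed no shift past the threshold in camera, at adjusted p = 0.732 with an estimated correlation. Higher distally were the spalt-like genes *sall1a*, from 133 ± 12.3 to 1005 ± 53.6, and *sall4*, from 12.3 ± 0.959 to 88.8 ± 8.27. The distal-less genes *dlx1a* and *dlx5a* rose 17.4-fold and 4.25-fold, and *sp8a* and *sp9*, known from the apical ectodermal ridge of limb buds, 5.2002-fold and 6.86-fold, *sp8a* from 229 ± 76.5 to 1193 ± 252. Lower distally were the proximal limb marker genes *meis1a*, from 181 ± 10.4 to 44.7 ± 7.50, and *meis2a*, from 183 ± 43.3 to 45.2 ± 8.69, together with *irx1a*, 7.89-fold. The Aristaless-type gene *alx4b* fell from 18.6 ± 6.13 to 1.12 ± 0.795; its mean over both positions lies below 10, so it is not tested where genes need a mean of at least 10. The HOX list had 12 of 46 measured members higher and 1 lower (11 and 1 adjusted over the list alone), and its lower calls were fewer than in other genes by Fisher's exact test (adjusted p = 0.00744, and 0.252 for higher calls). For a shift of the HOX list as a whole, camera gave adjusted p = 0.680 with an estimated correlation. The posterior genes *hoxa13b* and *hoxa13a* rose from 519 ± 119 to 1030.0 ± 157 and from 181 ± 24.5 to 287 ± 26.4, *hoxa10b* from 59.6 ± 15.2 to 125 ± 25.2, and *hoxa1a* from 7.51 ± 2.76 to 25.1 ± 6.24. *hoxb13a*, the single HOX gene called lower, stood at 28.5 ± 7.42 and 3.73 ± 2.61, and the abundant *hoxc13b*, not called by the authors, stood at 402 ± 34.04 and 341 ± 25.9. Its limma call ended without distal library 4 or proximal library 3 (adjusted p = 0.0613 and 0.0547). In the authors' deposited table adjusted p over the called genes of both lists named here ran from 1.26e-109 for *sall1a* to 1.75e-05 for *hoxa1a*.

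Genes of FGF and of BMP and TGF-beta signalling were mostly higher distally. The BMP and TGF-beta list had 38 of 68 measured members higher and 7 lower (39 and 9 adjusted over the list alone), with Fisher's exact test at adjusted p = 5.80e-11 for higher calls, and camera held at adjusted p = 0.0162 with an estimated correlation. Besides *bmp4*, the activin subunit gene *inhbb* rose from 207 ± 39.5 to 758 ± 67.7 and *fstl1a* from 16.3 ± 6.87 to 185 ± 8.72, while the follistatin gene *fstb*, which encodes an activin and BMP antagonist, fell from 694 ± 68.1 to 116 ± 12.2. The FGF list had 21 of 38 measured members higher and 3 lower (21 and 3 adjusted over the list alone). Fisher's exact test gave adjusted p = 2.23e-06 for higher calls. Camera gave adjusted p = 0.0572 with an estimated and 7.00e-05 with the preset correlation. The FGF-responsive transcription factor genes *etv4* and *etv5b* rose 5.50-fold and 2.84-fold, to 565 ± 23.1 and 397 ± 19.9, and the feedback inhibitor gene *il17rd* rose from 265 ± 39.0 to 1157 ± 23.1. The FGF-binding protein gene *fgfbp2a* fell from 7146 ± 1096 to 1396 ± 188. The Wnt list had 23 of 63 measured members higher and 20 lower (25 and 20 adjusted over the list alone), both over-represented by Fisher's exact test (adjusted p = 0.00210 and 0.0260). The adjusted p of the Wnt list was 0.650 with an estimated correlation, and its lower calls were not over-represented among limma calls (adjusted p = 0.249). The median log2 fold change of the Wnt list was 0.18 and its mean −0.17, of opposite sign, and camera put it upward. Besides *wnt5a* and *sfrp2*, *sfrp1a* fell from 2031 ± 257 to 387 ± 45.4 and the ligand gene *wnt10b* from 67.9 ± 9.32 to 1.99 ± 1.53.

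The Hedgehog list had 7 of 21 measured members higher and 5 lower (7 and 5 adjusted over the list alone) and passed neither Fisher's exact test (adjusted p = 0.136 and 0.658). The median log2 fold change of the Hedgehog list was −0.14 and its mean −0.02, while camera put it upward. Its called members include the ligand gene *ihha*, from 35.6 ± 8.28 to 180.0 ± 21.5, the pathway target gene *hhip*, 3.02-fold higher, and the co-receptor gene *boc*, from 1228 ± 137 to 607 ± 132. Retinoic acid pathway members were called 11 higher and 8 lower of 34, or 11 and 10 adjusted over the list alone, with neither direction past Fisher's exact test (adjusted p = 0.0806 and 0.497). The retinoic acid degrading enzyme genes *cyp26b1* and *cyp26a1* rose from 784 ± 65.2 to 3151 ± 82.6 and from 2365 ± 549.7 to 7187 ± 778, and *bco1*, whose product makes retinal from beta-carotene, rose 6.77-fold. The receptor gene *raraa* fell from 269.8 ± 32.8 to 87.8 ± 16.9. Bioelectric and fin size genes were called 10 higher and 15 lower of 47, or 10 and 15 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.658 and 0.0510). The median log2 fold change of that list was 0.01 and its mean −0.31, of opposite sign. The T-type calcium channel gene *cacna1g* fell from 1585 ± 150.2 to 457 ± 44.2 and *hapln1b* from 98.5 ± 18.5 to 13.1 ± 3.29, whereas the semaphorin gene *sema3d* rose from 61.5 ± 19.7 to 184 ± 7.09. Over the named genes of the 6 signalling lists, adjusted p in the authors' deposited table ran from 9.09e-214 for *sfrp2* to 2.91e-12 for *boc*.

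**Figure D2:**
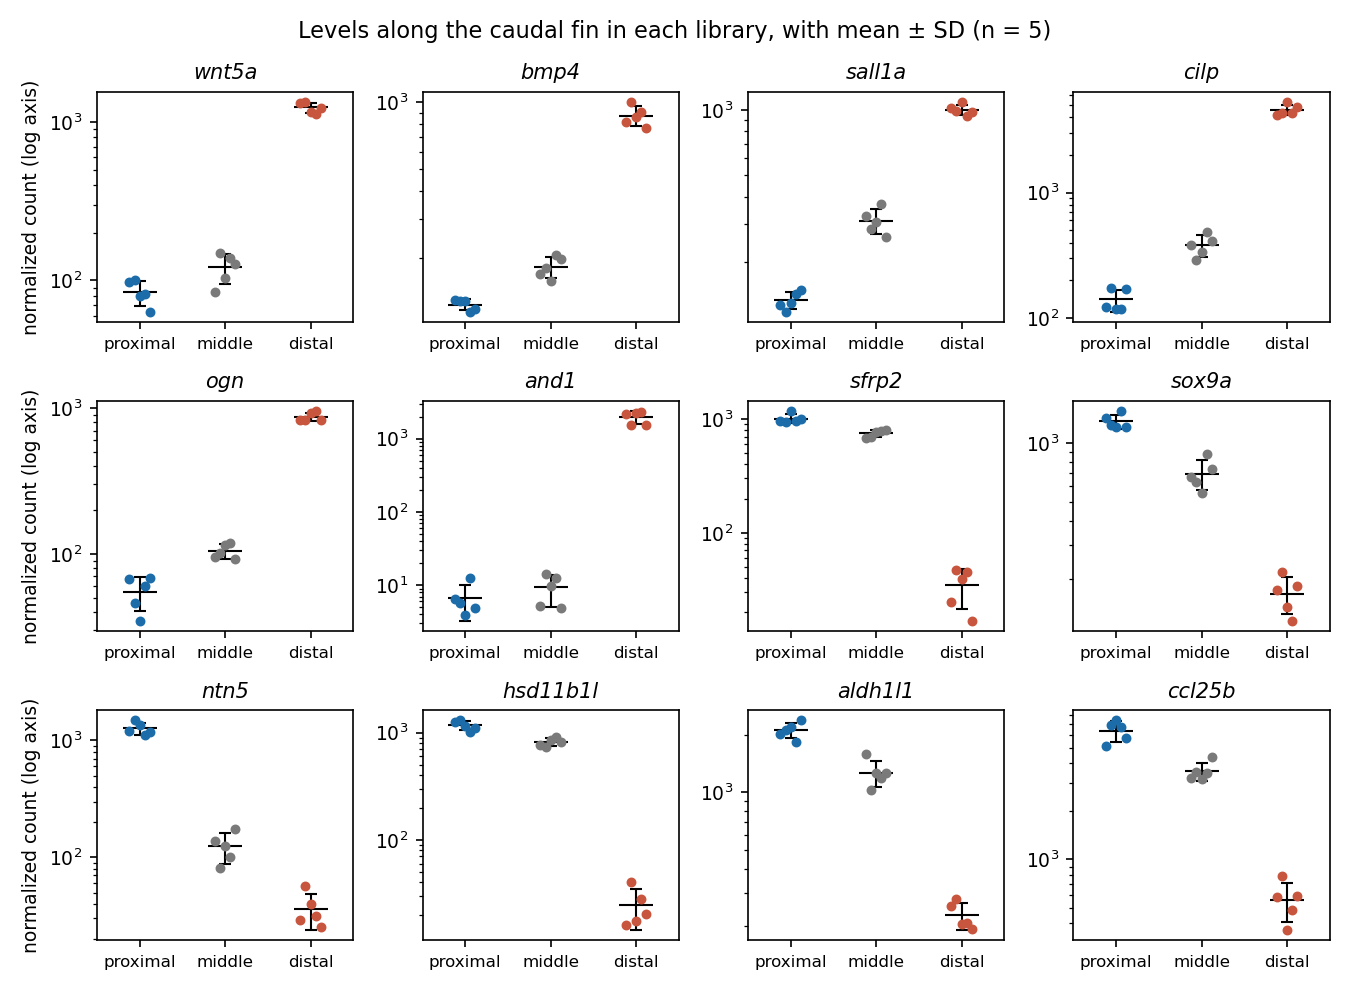
Normalized counts (log axis) of 12 named genes in each of the 15 fin libraries by position, 1 point per library, with the mean and SD of 5 libraries as bars. Distal points of *wnt5a*, *bmp4*, *sall1a*, *cilp*, *ogn* and *and1* lie above every proximal point, and those of *sfrp2*, *sox9a*, *ntn5*, *hsd11b1l*, *aldh1l1* and *ccl25b* below every proximal point.

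Osteoblast and bone matrix members were called 21 higher and 4 lower of 41, or 23 and 5 adjusted over the list alone. They were over-represented among higher genes by Fisher's exact test (adjusted p = 1.03e-05). Camera gave adjusted p = 0.368 with an estimated and 0.000408 with the preset correlation. The fibrillar collagen gene *col11a1a* rose from 444 ± 109 to 2589 ± 178, the lysyl hydroxylase gene *plod2* from 127 ± 31.0 to 708 ± 78.3, and *entpd5a*, needed for bone mineralization, from 159.9 ± 41.4 to 506 ± 50.9. Cartilage members were called 10 higher and 12 lower of 29, or 10 and 13 adjusted over the list alone. The lower calls passed Fisher's exact test (adjusted p = 0.0107) and the higher ones did not (adjusted p = 0.0615). The adjusted p of the cartilage list was 0.907 with an estimated correlation, and its lower calls were not over-represented among limma calls (adjusted p = 0.0852). The median log2 fold change was −0.50 over the measured members and −0.12 over the 23 of them in camera, which put the list upward. Its members include *cilp*, from 141 ± 28.3 to 4553 ± 426, and the matrilin gene *matn4*, from 99.2 ± 33.5 to 1368 ± 176, as well as *sox9a*. Fin ray joint and distal ray genes were called 9 higher and 8 lower of 23, or 9 and 9 adjusted over the list alone, with adjusted p = 0.0391 for higher calls by Fisher's exact test and adjusted p = 0.99 with an estimated correlation. Their median log2 fold change was −0.00 and their mean 0.31, of opposite sign. Their higher calls were not over-represented among limma calls (adjusted p = 0.185). The fibronectin gene *fn1b* was 8.85-fold higher and the hyaluronan link protein gene *hapln1a* 11.8-fold lower distally in the authors' deposited table. The hyaluronan synthase gene *has2* fell from 153 ± 13.7 to 24.5 ± 9.08.

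Osteoclast markers were called 6 higher and 1 lower of 15, or 6 and 1 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.0774 and 0.627); the metalloprotease gene *mmp14a* rose from 1067 ± 92.8 to 2039.7 ± 48.8 and the receptor gene *csf1rb* fell from 88.2 ± 21.8 to 35.4 ± 7.85. Vascular smooth muscle and fibroblast markers were called 17 higher and 15 lower of 45, or 17 and 16 adjusted over the list alone, both past Fisher's exact test (adjusted p = 0.00624 and 0.0490). The adjusted p of that list was 0.907 with an estimated correlation, and its lower calls were not over-represented among limma calls (adjusted p = 0.172). Its higher calls were lost with positions scaled to equal totals of all genes (adjusted p = 0.141, Fisher's exact test). The median log2 fold change was 0.10 and the mean −0.05, of opposite sign. The collagen VI gene *col6a6* rose from 497 ± 105 to 5505 ± 321 and the thrombospondin gene *thbs4b* from 730.2 ± 75.6 to 4292 ± 239, while the elastin gene *elna* fell from 275 ± 20.9 to 76.5 ± 23.9. Over the named skeletal, matrix and fibroblast genes, adjusted p in the authors' deposited table ran from 2.44e-267 for *cilp* to 1.88e-06 for *csf1rb*.

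All 3 pigment cell lists held more calls than other genes in a direction. Melanophore markers were called 15 higher and 0 lower of 19, or 15 and 0 adjusted over the list alone. Fisher's exact test gave adjusted p = 2.13e-07 for higher calls. Camera gave adjusted p = 0.218 with an estimated and 6.65e-06 with the preset correlation. The melanin synthesis genes *tyrp1b* and *dct* rose from 472 ± 91.7 to 2476 ± 404 and from 13.9 ± 5.62 to 92.0 ± 20.4, and the melanosome transport gene *mlpha* rose from 319 ± 10.9 to 843 ± 64.3. Xanthophore markers were called 12 higher and 4 lower of 20, or 12 and 4 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000182 for higher calls). Camera gave adjusted p = 0.368 with an estimated and 0.00131 with the preset correlation. Higher were *scarb1*, a carotenoid uptake receptor gene, from 401 ± 30.4 to 1715 ± 175, and *aox5*, from 281 ± 27.8 to 999.5 ± 149, and lower was *sprb*, a gene of pteridine synthesis, from 108 ± 16.4 to 19.1 ± 4.605. Iridophore markers were called 8 higher and 9 lower of 22, or 9 and 9 adjusted over the list alone, the lower calls past Fisher's exact test (adjusted p = 0.0322) and the higher ones not (adjusted p = 0.0825). The adjusted p of the iridophore list was 0.907 with an estimated correlation, and its lower calls were not over-represented among limma calls (adjusted p = 0.132). The scaffold gene *akap12a* fell from 1024 ± 144 to 128 ± 42.2, *fhl2b* 10.5-fold and *gpnmb* 4.97-fold, while *ednrbb* is a list member that rose. In the authors' deposited table adjusted p over these pigment cell genes ran from 2.16e-69 for *scarb1* to 2.66e-19 for *dct*.

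Epidermal markers were mostly higher distally and markers of ionocytes and mucous cells mostly lower. The epidermis list had 38 of 58 measured members higher and 8 lower (39 and 8 adjusted over the list alone). Fisher's exact test gave adjusted p = 7.94e-14 for higher calls. Camera gave adjusted p = 0.218 with an estimated and 3.49e-06 with the preset correlation. The basement membrane genes *frem1a* and *frem2a* rose from 62.9 ± 9.10 to 537 ± 57.8 and from 89.5 ± 10.4 to 508 ± 50.1, and the annexin gene *anxa1c* from 1059.5 ± 79.9 to 3546 ± 239. The ionocyte and mucous cell list had 2 of 24 measured members higher and 16 lower (2 and 17 adjusted over the list alone), with Fisher's exact test at adjusted p = 2.23e-06 for lower calls, and camera held at adjusted p = 0.0162 with an estimated correlation. The mucin gene *muc5.1* fell from 1962 ± 514 to 79.8 ± 53.7 and the transcription factor gene *foxa3*, which acts in mucus-secreting cells, from 172 ± 23.6 to 16.04 ± 4.26. The carbonic anhydrase gene *ca2*, 1 of 2 members called higher, rose from 2978 ± 338 to 11281 ± 1713. Adjusted p over these 6 genes in the authors' deposited table ran from 3.97e-97 for *frem1a* to 1.63e-29 for *ca2*.

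Leukocyte markers were called 5 higher and 24 lower of 55, or 6 and 24 adjusted over the list alone. Fisher's exact test gave adjusted p = 6.62e-05 for lower calls. Camera gave adjusted p = 0.680 with an estimated and 0.0221 with the preset correlation. The chemokine gene *ccl25b* fell from 6406 ± 945 to 559 ± 155, the lymphocyte kinase gene *itk* from 83.8 ± 9.68 to 28.4 ± 1.48 and the lysozyme gene *lyz* from 114 ± 27.8 to 24.4 ± 17.3. Endothelial markers were called 17 higher and 9 lower of 42, or 17 and 9 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00364 for higher calls). The adjusted p of the endothelium list was 0.732 with an estimated correlation and 0.0888 by Fisher's exact test on limma calls. Its median log2 fold change was 0.15 and its mean −0.02, of opposite sign. The tight junction gene *cldn5b* rose from 119 ± 21.1 to 469 ± 58.7 and the von Willebrand factor gene *vwf* fell from 260.1 ± 41.4 to 135 ± 22.1. Skeletal muscle markers were called 3 higher and 15 lower of 51, or 3 and 15 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.0605 and 0.0825), though their lower calls were past it among limma calls (adjusted p = 0.0274; adjusted p = 0.218 with an estimated correlation). The sarcomere genes *myom1b* and *ttna* fell from 146 ± 15.7 to 3.85 ± 0.620 and from 306 ± 55.1 to 61.2 ± 11.3. Nerve and Schwann cell markers were called 8 higher and 13 lower of 39, or 8 and 14 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.739 and 0.0510). The myelin genes *mbpa* and *plp1b* fell 5.58-fold and 6.39-fold, and *erbb3a* rose from 2017 ± 282 to 6557 ± 726. Erythrocyte markers were called 7 higher and 2 lower of 19, or 8 and 2 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.111 and 0.658); the beta-globin gene *ba1* rose from 82.2 ± 66.9 to 416 ± 246. Adipocyte markers were called 4 higher and 9 lower of 28, or 5 and 10 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.835 and 0.136); *dgat2*, which acts in triglyceride synthesis, rose from 94.1 ± 20.2 to 1055 ± 297. Over these named markers, adjusted p in the authors' deposited table ran from 3.65e-77 for *myom1b* to 0.00479 for *ba1*.

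Amino acid and one-carbon metabolism was the metabolic list with the most lower calls. It had 11 of 73 measured members higher and 33 lower (11 and 35 adjusted over the list alone). Fisher's exact test gave adjusted p = 1.24e-06 for lower calls. Camera gave adjusted p = 0.301 with an estimated and 0.000408 with the preset correlation. The folate enzyme gene *aldh1l1* fell from 2110.5 ± 197 to 228 ± 36.4, the methionine cycle genes *mat1a* and *bhmt* from 639 ± 53.6 to 125 ± 21.1 and from 3259 ± 244 to 857 ± 103, and *cbsa* 9.70-fold. Mitochondrial respiration members were called 5 higher and 15 lower of 77, or 4 and 15 adjusted over the list alone. Their higher calls were fewer than in other genes by Fisher's exact test (adjusted p = 0.0229). This was lost when positions were scaled to equal totals of all genes (adjusted p = 0.643, Fisher's exact test). For a shift of the list as a whole, camera gave adjusted p = 0.927 with an estimated correlation. The list's median log2 fold change was 0.00 and its mean −0.06. Mitochondrially encoded *mt-nd4* fell from 9635 ± 881 to 6123 ± 734. Glycolysis members were called 5 higher and 5 lower of 35, or 5 and 5 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.839 and 0.739), with a median log2 fold change of −0.09 and a mean of 0.07. The lactate dehydrogenase gene *ldhba* rose from 2139 ± 103 to 3194 ± 148. Cell cycle members were called 8 higher and 3 lower of 64, or 7 and 3 adjusted over the list alone. Lower calls were fewer than in other genes by Fisher's exact test (adjusted p = 0.0107). For a shift of the cell cycle list as a whole, camera gave adjusted p = 0.969 with an estimated correlation. The median of this list was −0.03, while camera put it upward. Immediate early and stress response members were called 17 higher and 9 lower of 55, or 20 and 9 adjusted over the list alone, not past Fisher's exact test (adjusted p = 0.0510 and 0.862), though their higher calls were past it where genes were called at a threshold of 0.1 (adjusted p = 0.00962; adjusted p = 0.680 with an estimated correlation). The matricellular gene *ctgfb* rose from 211 ± 28.8 to 736 ± 119 and *klf4* from 4572 ± 713 to 12186 ± 1918. Adjusted p over these named genes in the authors' deposited table ran from 2.61e-145 for *aldh1l1* to 5.47e-07 for *ldhba*.

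**Figure D3:**
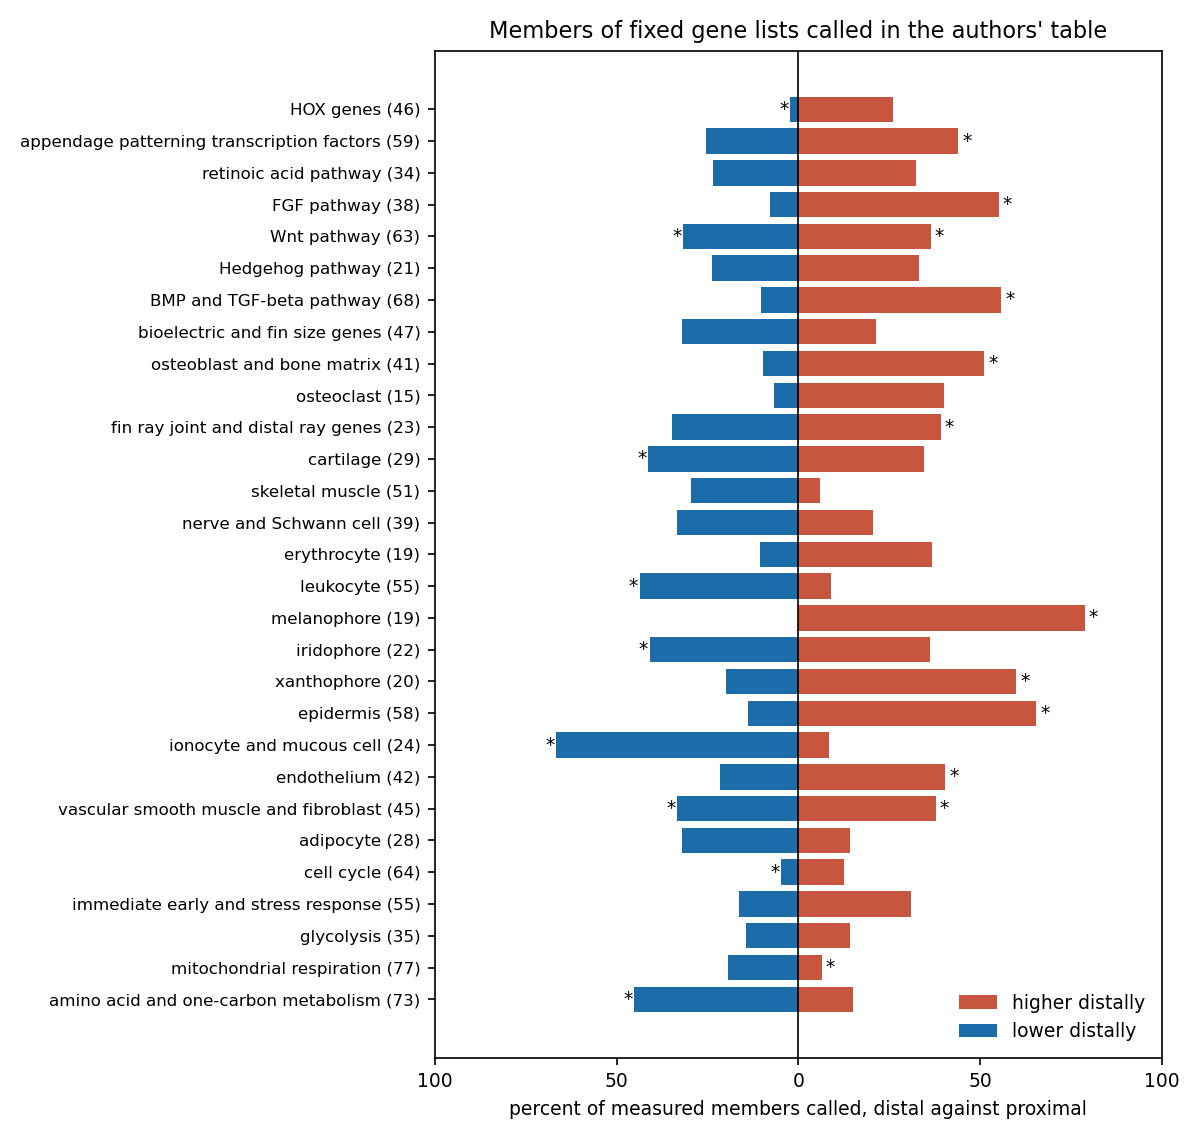
Percent of the measured members (numbers in brackets) of 29 fixed gene lists called higher (right) or lower (left) in the distal against the proximal fin at an adjusted p under 0.05 in the authors' deposited table. Asterisks mark adjusted p under 0.05 in a two-sided Fisher's exact test. They stand for too few calls in the lower bars of HOX and cell cycle genes and in the higher bar of mitochondrial respiration. In camera, a test of a shift of the whole list, only the BMP and TGF-beta and the ionocyte and mucous cell lists passed with an estimated correlation. With the preset correlation 9 lists passed.

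Scaling by the totals of uniquely solved genes moved all genes by a median −0.08, so medians close to 0 changed sign by that shift: those of the retinoic acid, bioelectric, osteoclast, fin ray joint and mitochondrial lists over the members in the limma fit turned negative. For the 21 fin ray joint members in that fit, the median was 0.00 with size factors and −0.08 with those totals. With positions scaled to equal totals of all genes, that of the cell cycle list turned positive. Of the 8415 calls, 3123 also had an absolute log2 fold change of at least 1 in the authors' deposited table. The tests are the authors' DESeq tests per gene and two-sided Fisher's exact tests per list, whose p treats genes as independent; a fit with limma to the recovered counts called 9731 of 18871 genes. The balance of limma calls depended on scaling: 50.1% were higher distally with size factors, 41.0% (4070 higher and 5868 lower) by totals of uniquely solved genes and 57.8% (5669 and 4135) with positions scaled to equal totals of all genes.

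Fewer genes differed between the middle and the proximal fin than between the distal and the proximal fin. The keratin gene *krtt1c19e* stood at 5025 ± 770.4 normalized counts proximally and 21583 ± 2576 in the middle, 4.29-fold higher. The homeobox gene *emx2* rose from 12.3 ± 7.90 to 72.4 ± 13.9, the pentraxin gene *crp7* from 10.7 ± 5.23 to 47.8 ± 12.5, the ferlin gene *otofb* from 12.3 ± 6.75 to 86.6 ± 22.2 and *fndc7b* from 22.3 ± 10.5 to 111 ± 27.2. In the other direction, the netrin gene *ntn5* fell from 1269 ± 152 to 124 ± 36.2. Of genes with a mean of at least 20 over both positions, the 5 largest falls were those of the mesothelin gene *mslna*, from 151 ± 61.7 to 4.31 ± 1.13, and of 4 genes that varied widely between proximal libraries. Of these, *scpp7* and *scpp6* had no read in any middle library, with 247 ± 280.4 and 125 ± 122 proximally, at least 435-fold and 219.7-fold lower. Without proximal library 2, which held 716 and 327, these bounds were 228-fold and 131-fold. The others, *paplnb* and *c6ast1*, stood at 2.55 ± 2.39 and 0.899 ± 1.25 in the middle. The limma call of *paplnb* ended without middle library 2, 3 or 5 (adjusted p = 0.0547, 0.0517 and 0.0529). Adjusted p over these 11 genes in the authors' deposited table ran from 1.63e-88 for *ntn5* to 0.000905 for *c6ast1*.

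Of 23556 genes in the authors' deposited table for this pair, 1721 were called, 827 higher in the middle and 894 lower. Xanthophore markers were called 10 higher and 0 lower of 20, or 13 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 1.05e-08; adjusted p = 0.0831 with an estimated correlation), with *scarb1* rising from 401 ± 30.4 to 755 ± 37.5 and *aox5* from 281 ± 27.8 to 533 ± 52.5. Epidermis members were called 18 higher and 3 lower of 58, or 21 and 4 adjusted over the list alone (Fisher's exact test, adjusted p = 3.81e-11; adjusted p = 0.140 with an estimated correlation), *anxa1c* rising 1.43-fold. Cell cycle members were called 8 higher and 0 lower of 64, or 9 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00775; adjusted p = 0.630 with an estimated correlation). The replication clamp gene *pcna* rose from 934 ± 119 to 1276 ± 211. Osteoblast and bone matrix members were called 7 higher and 1 lower of 41, or 8 and 3 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00285; adjusted p = 0.813 with an estimated correlation), and the periostin gene *postnb* rose from 7319 ± 507 to 15313 ± 1248. Melanophore markers were called 4 higher and 0 lower of 18, or 5 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0129; adjusted p = 0.324 with an estimated correlation), a call lost when positions were scaled to equal totals of all genes (adjusted p = 0.0890).

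Several lists held more lower calls than other genes. Ionocyte and mucous cell markers were called 2 higher and 9 lower of 26, or 2 and 12 adjusted over the list alone (Fisher's exact test, adjusted p = 5.30e-06 for lower calls; adjusted p = 0.0507 with an estimated correlation), *foxa3* falling from 172 ± 23.6 to 102 ± 14.7. Appendage patterning transcription factors were called 5 higher and 12 lower of 57, or 6 and 20 adjusted over the list alone (Fisher's exact test, adjusted p = 1.41e-05 for lower calls; adjusted p = 0.682 with an estimated correlation). *lmx1bb* fell from 135 ± 38.5 to 26.3 ± 10.9, *lhx9* from 114 ± 9.43 to 60.5 ± 3.51 and *pbx4* from 708 ± 39.9 to 505 ± 37.1. Fin ray joint and distal ray genes were called 2 higher and 8 lower of 22, or 3 and 9 adjusted over the list alone (Fisher's exact test, adjusted p = 1.20e-05 for lower calls; adjusted p = 0.461 with an estimated correlation), among them *has2*, which fell from 153 ± 13.7 to 98.5 ± 11.6. Wnt members were called 4 higher and 12 lower of 62, or 6 and 15 adjusted over the list alone (Fisher's exact test, adjusted p = 3.01e-05 for lower calls; adjusted p = 0.227 with an estimated correlation), with *wnt10b* falling from 67.9 ± 9.32 to 13.7 ± 2.63. Hedgehog members were called 1 higher and 6 lower of 21, or 1 and 8 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000810 for lower calls; adjusted p = 0.315 with an estimated correlation), with *boc* falling from 1228 ± 137 to 802 ± 116 and *hhip* from 125 ± 10.8 to 87.2 ± 10.7. Over the named genes of these lists, adjusted p in the authors' deposited table ran from 1.12e-21 for *postnb* to 0.0242 for *pcna*.

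Other lists also passed Fisher's exact test. Retinoic acid pathway members were called 5 higher and 7 lower of 35, or 5 and 8 adjusted over the list alone (adjusted p = 0.0244 and 0.00213; adjusted p = 0.837 with an estimated correlation). BMP and TGF-beta members were called 7 higher and 4 lower of 68, or 10 and 4 adjusted over the list alone (adjusted p = 0.0296 for higher calls; adjusted p = 0.682 with an estimated correlation). Bioelectric and fin size genes were called 2 higher and 6 lower of 47, or 3 and 7 adjusted over the list alone (adjusted p = 0.0270 for lower calls; adjusted p = 0.505 with an estimated correlation). Both were lost with positions scaled to equal totals of all genes (adjusted p = 0.0524 and 0.0890). Iridophore markers were called 4 higher and 2 lower of 22, or 4 and 3 adjusted over the list alone (adjusted p = 0.0244 for higher calls; adjusted p = 0.837 with an estimated correlation). Lower calls passed among cartilage members, called 4 higher and 6 lower of 30, or 4 and 6 adjusted over the list alone (adjusted p = 0.00386; adjusted p = 0.837 with an estimated correlation). They also passed among vascular smooth muscle and fibroblast markers, called 5 higher and 6 lower of 45, or 5 and 6 adjusted over the list alone (adjusted p = 0.0244; adjusted p = 0.837 with an estimated correlation). Adipocyte markers were called 1 higher and 6 lower of 28, or 1 and 7 adjusted over the list alone (adjusted p = 0.00285 for lower calls; adjusted p = 0.461 with an estimated correlation). Amino acid and one-carbon members were called 6 higher and 10 lower of 73, or 7 and 10 adjusted over the list alone (adjusted p = 0.00271 for lower calls; adjusted p = 0.837 with an estimated correlation). On limma calls Fisher's exact test no longer passed for higher retinoic acid and iridophore members (adjusted p = 0.157 for both), nor for lower cartilage (0.0642), vascular (0.157), adipocyte (0.0642) and amino acid (0.143) members.

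Of the 1721 calls for middle vs proximal, 486 had an absolute log2 fold change of at least 1 in the authors' deposited table and 1132 an adjusted p under 0.01, and limma called 2614 genes, 1304 higher and 1310 lower. With positions scaled to equal totals of all genes, limma called 2935, of which 1897 (64.6%) were higher, against 49.9% higher with size factors. By totals of uniquely solved genes, 1123 of 2634 (42.6%) were higher. Scaling to equal totals moved all genes by a median 0.05, which turned the medians of 7 lists positive over the members in the limma fit: retinoic acid, bioelectric, osteoclast, cartilage, endothelium, vascular, and immediate early and stress response. The totals of uniquely solved genes, with a shift of −0.03, turned those of the FGF and the amino acid lists negative.

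The distal fin differed from the middle fin in 6077 of 23232 genes of the authors' deposited table, 3084 higher and 2993 lower, and the actinodin genes that set the distal fin apart from the proximal fin differed here too. *and1* stood at 9.34 ± 4.31 in the middle and 1960.0 ± 391 distally, and *and2* at 0.772 ± 1.26 and 169 ± 54.0. Among genes with a mean of at least 20 over both positions, both genes named *otud4* were again among the 5 largest rises, with the distal reads in 3 libraries. *zic2b* had no read in any middle library and 47.1 ± 11.1 normalized counts distally, at least 83.1-fold higher. *mslna*, low in the middle at 4.31 ± 1.13, stood at 244 ± 51.5 distally, and *thbs4b* rose from 711 ± 60.4 to 4292 ± 239. The largest falls of such genes were *fabp1b.2*, from 2224 ± 539 to 1.96 ± 1.78, *fndc7a*, from 73.2 ± 18.4 to 1.57 ± 1.25, *fndc7b*, from 111 ± 27.2 to 3.04 ± 2.98, and the RNA-binding protein gene *khdrbs2*, from 41.4 ± 8.39 to 1.12 ± 0.795, together with *muc5.2*. In the authors' deposited table *muc5.2* was 39.5-fold lower distally, and adjusted p over these 12 genes ran from 2.66e-117 for *thbs4b* to 0.0115 for *otud4* ENSDARG00000087337.

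The BMP and TGF-beta, FGF, Wnt and Hedgehog lists held more higher than lower calls. BMP and TGF-beta members were called 39 higher and 7 lower of 68, or 39 and 7 adjusted over the list alone (Fisher's exact test, adjusted p = 7.68e-16 for higher calls), FGF members 22 higher and 2 lower of 37, or 22 and 3 adjusted over the list alone (adjusted p = 1.15e-09, Fisher's exact test). Both held in camera, at adjusted p = 0.0106 and 0.0141 with an estimated correlation. *bmp4* rose from 182 ± 19.8 to 871 ± 88.5 and *etv4* from 128 ± 16.3 to 565 ± 23.1. Appendage patterning transcription factors were called 29 higher and 8 lower of 57, or 29 and 10 adjusted over the list alone (Fisher's exact test, adjusted p = 3.20e-10; adjusted p = 0.335 with an estimated correlation), and Wnt members 23 higher and 12 lower of 61, or 26 and 13 adjusted over the list alone (Fisher's exact test, adjusted p = 1.03e-05; adjusted p = 0.226 with an estimated correlation). *sall1a* rose from 309 ± 41.8 to 1005 ± 53.6, *lhx9* from 60.5 ± 3.51 to 122 ± 29.0 and *wnt5a* from 121 ± 26.2 to 1235 ± 91.7. Hedgehog members were called 9 higher and 4 lower of 21, or 10 and 6 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00281; adjusted p = 0.385 with an estimated correlation), a call lost when positions were scaled to equal totals of all genes (adjusted p = 0.0592). *hhip*, lower in the middle than proximally, rose from 87.2 ± 10.7 to 378 ± 18.97. Osteoblast and bone matrix members were called 19 higher and 3 lower of 41, or 19 and 3 adjusted over the list alone (Fisher's exact test, adjusted p = 2.23e-06; adjusted p = 0.335 with an estimated correlation), although *postnb* fell from 15313 ± 1248 to 7378 ± 517.

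Among cell type lists, ionocyte and mucous cell markers were called 2 higher and 12 lower of 24, or 2 and 13 adjusted over the list alone, with Fisher's exact test at adjusted p = 7.13e-05 for lower calls, and held in camera at adjusted p = 0.0141 with an estimated correlation. *muc5.1* fell from 1255 ± 89.1 to 79.8 ± 53.7. Leukocyte markers were called 1 higher and 27 lower of 55, or 1 and 27 adjusted over the list alone (Fisher's exact test, adjusted p = 1.19e-09 for lower calls; adjusted p = 0.335 with an estimated correlation), *ccl25b* falling from 3557 ± 479 to 559 ± 155. Melanophore markers were called 11 higher and 0 lower of 19, or 12 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 3.86e-05; adjusted p = 0.226 with an estimated correlation) and epidermis members 27 higher and 9 lower of 58, or 31 and 10 adjusted over the list alone (Fisher's exact test, adjusted p = 7.23e-09; adjusted p = 0.340 with an estimated correlation). *tyrp1b* rose from 754 ± 172 to 2476 ± 404 and *frem1a* from 55.6 ± 13.2 to 537 ± 57.8, whereas *krtt1c19e* fell from 21583 ± 2576 to 1985 ± 836. Cell cycle members were called 1 higher and 7 lower of 64, or 1 and 3 adjusted over the list alone. Higher calls were fewer than in other genes (Fisher's exact test, adjusted p = 0.00753). For a shift of the list as a whole, camera gave adjusted p = 0.665 with an estimated correlation. Amino acid and one-carbon members were called 8 higher and 31 lower of 72, or 9 and 34 adjusted over the list alone (Fisher's exact test, adjusted p = 2.62e-09 for lower calls; adjusted p = 0.226 with an estimated correlation), *aldh1l1* falling from 1267 ± 201 to 228 ± 36.4. Over the named genes of these lists, adjusted p in the authors' deposited table ran from 1.24e-188 for *muc5.1* to 2.52e-05 for *lhx9*. Of the 6077 calls, 1914 had an absolute log2 fold change of at least 1 in the authors' deposited table. Of limma calls 52.6% were higher distally with size factors, 43.0% by totals of uniquely solved genes and 55.0% with positions scaled to equal totals of all genes. The totals of uniquely solved genes, with a shift of all genes by −0.05, turned the median of the adipocyte list negative.

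Higher calls also passed Fisher's exact test among erythrocyte markers, called 9 higher and 2 lower of 20, or 9 and 2 adjusted over the list alone (adjusted p = 0.00206; adjusted p = 0.665 with an estimated correlation). Endothelial markers were called 15 higher and 3 lower of 42, or 15 and 3 adjusted over the list alone (adjusted p = 0.000866 for higher calls; adjusted p = 0.340 with an estimated correlation). Vascular smooth muscle and fibroblast markers were called 15 higher and 10 lower of 45, or 15 and 12 adjusted over the list alone (adjusted p = 0.00190 for higher calls; adjusted p = 0.665 with an estimated correlation). Immediate early and stress response members were called 18 higher and 5 lower of 55, or 18 and 5 adjusted over the list alone (adjusted p = 0.000810 for higher calls; adjusted p = 0.381 with an estimated correlation). Retinoic acid members were called 12 higher and 6 lower of 33, or 12 and 7 adjusted over the list alone (adjusted p = 0.00252 for higher calls; adjusted p = 0.340 with an estimated correlation). Osteoclast markers were called 7 higher and 2 lower of 15, or 7 and 2 adjusted over the list alone (adjusted p = 0.00563 for higher calls; adjusted p = 0.335 with an estimated correlation). On limma calls Fisher's exact test no longer passed for either (adjusted p = 0.0644 and 0.103). Lower calls of bioelectric and fin size genes, called 11 higher and 12 lower of 46, or 12 and 13 adjusted over the list alone, passed too (adjusted p = 0.0290; adjusted p = 0.687 with an estimated correlation), but not on limma calls (adjusted p = 0.103). Both directions passed Fisher's exact test for 4 lists. Fin ray joint genes were called 8 higher and 7 lower of 22, or 9 and 7 adjusted over the list alone. Cartilage members were called 9 higher and 8 lower of 28, or 9 and 8 adjusted over the list alone. Iridophore markers were called 8 higher and 8 lower of 22, or 8 and 8 adjusted over the list alone. Xanthophore markers were called 7 higher and 7 lower of 20, or 10 and 7 adjusted over the list alone. Their adjusted p was 0.687, 0.665, 0.687 and 0.558 with an estimated correlation. On limma calls neither direction passed for the first 3, nor the lower one for xanthophores (adjusted p = 0.221). The higher one for xanthophores was lost among genes with a mean of at least 10 (adjusted p = 0.0561). Mitochondrial respiration members were called 0 higher and 6 lower of 77, or 0 and 4 adjusted over the list alone. Higher calls were fewer than in other genes (adjusted p = 0.000150, Fisher's exact test). For a shift of that list as a whole, camera gave adjusted p = 0.665 with an estimated correlation. HOX genes were called 9 higher and 1 lower of 46, or 8 and 1 adjusted over the list alone. Lower calls were fewer than in other genes (adjusted p = 0.0491, Fisher's exact test). For a shift of the HOX list as a whole, camera gave adjusted p = 0.551 with an estimated correlation. The HOX call was lost without genes that are in another list (adjusted p = 0.0526).

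Of the 8415 end-to-end calls, 7131 (84.7%) had their 3 means in order, 3544 rising and 3587 falling towards the tip, with no test of either step. Among the genes that the authors list as monotonic, those with the smallest end-to-end adjusted p include the matrix genes *cilp* and *col6a6* and the small proteoglycan gene *ogn*. From proximal to distal, *cilp* stood at 141 ± 28.3, 382 ± 75.3 and 4553 ± 426, *col6a6* at 497 ± 105, 1192 ± 136 and 5505 ± 321, and *ogn* at 55.2 ± 14.5, 104 ± 12.01 and 873 ± 59.6. The chemokine gene *cxcl14* stood at 116 ± 25.1, 194 ± 47.4 and 1228 ± 84.2. Falling in order were the steroid dehydrogenase gene *hsd11b1l*, at 1170.0 ± 113, 818 ± 71.0 and 24.5 ± 10.1, *abi3bpa*, at 572 ± 39.8, 200.02 ± 17.4 and 8.13 ± 7.57, and *ntn5*, at 1269 ± 152, 124 ± 36.2 and 36.4 ± 12.4. The authors' deposited table of monotonic genes lists 1144 genes, 631 rising and 513 falling, and all of them are among the 7131 with the same direction. Every listed gene, and no other, had the same sign and an adjusted p under 0.1 in both neighbouring comparisons. Requiring an adjusted p under 0.05 in both neighbouring comparisons left 877 genes, and requiring each step to reach 10% of the mean left 4751.

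The change was split unevenly between the steps from proximal to middle and from middle to distal. The distances between the sampled regions are not given here, so the split says nothing of change per length of fin. Among 1043 called genes higher distally with an absolute log2 fold change of at least 1 and a mean of at least 20, the proximal to middle step held a median 30.0% of the end-to-end log2 change of the means with 1 added (quartiles 15.8% to 41.2%), and under 50% in 904 genes. Among 976 such genes lower distally the median was 28.0% (quartiles 13.2% to 43.4%), under 50% in 808. Individual genes departed from this. *ntn5* fell 10.204-fold from proximal to middle and 3.42-fold from middle to distal, and *hoxa13b* stood at 519 ± 119, 879 ± 201 and 1030.0 ± 157.

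The 3 tables rest on the same libraries, so the end-to-end log2 fold change equals the sum of the neighbouring ones by construction, apart from scaling. Over 22737 genes the difference had a median of 0.0073 and was at most 0.0189. Distal fin calls against the proximal and against the middle fin shared 2714 higher and 2545 lower genes, where independent lists would share 561 and 540. Calls of both outer positions against the proximal fin shared 689 higher and 747 lower genes, against 147 and 164. Genes called higher at both neighbouring steps numbered 479 and lower at both 398, against 110 and 113. Genes called highest in the middle numbered 113 against 108 for independent lists, and genes called lowest there 110 against 115. Each pair of comparisons shares 5 libraries. Across the 18726 genes fitted by limma for the shared-library test, which are not independent replicates, the covariance of the log2 fold changes sharing the distal libraries was 0.551. It was 0.529 with those libraries split between the comparisons and 0.0233 in simulated unchanged groups, with Pearson r = 0.888, 0.821 and 0.512. Sharing the proximal libraries gave 0.225, 0.204 and 0.0222 (r = 0.619, 0.528 and 0.495), and sharing the middle libraries 0.0549, 0.0752 and −0.0220 (r = 0.189, 0.234 and −0.491). No gene was called in both comparisons in any of 20 simulations with limma, in which every gene was unchanged. They do not show how many shared calls the shared libraries give among genes that differ.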

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

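The test of normalization below was fixed before its result was seen; the tests of cell shares, library depth and shared fish or handling were chosen only after the results were seen.

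Of 408 groups of 5 libraries, 19 held a library whose gap to its nearest neighbour was large against the range of its group, where chance gives 20.4. Distally, *pnocb* was low in 1 library, at 27.7 normalized counts against 44.9 to 48.2 in the others. *hoxa1a* was high in 1 distal library, at 36.2 against 21.3 to 23.5, *mbpa* at 109.9 against 76.0 to 79.7, *muc5.1* at 175 against 45.8 to 67.3 and *kif20a* at 41.5 against 26.5 to 29.9. The distal fin also held single high values of *bhmt*, at 1035 against 771 to 838, *cbsa*, at 33.1 against 17.96 to 21.3, *abi3bpa*, at 21.3 against 2.196 to 6.62, and *krtt1c19e*, at 3457 against 1511 to 1869. *galnt8b.2* was read in 1 distal library, at 0.945, and *otud4* ENSDARG00000087337 in 1 proximal library, at 0.967. That *otud4* gene reached 3959 in 1 distal library against 0 to 562 in the others. Proximally, *meis2a* was low in 1 library, at 108 against 183 to 212, while *sfrp2* was high at 1164 against 947 to 999, *cacna1g* at 1844 against 1464 to 1567 and *ca2* at 3578 against 2782 to 2898. In the middle, *aox5* was low in 1 library, at 439.9 against 543 to 564, and *ca2* high, at 6079 against 4418 to 4894. On the first principal component, 1 distal library lay at 60.0 against 70.6 to 74.1.

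Melanophore markers were higher and mucous cell markers lower distally, the first at adjusted p = 0.218 in camera with an estimated correlation and 6.65e-06 with the preset one. With counts scaled by the totals of uniquely solved genes, limma called 15 of 18 melanophore markers higher, as with size factors. With positions scaled to equal totals of all genes it called 16. This test of normalization could hardly come out otherwise: those totals moved all genes by a median −0.08, against a melanophore median of 1.13. Of 21 ionocyte and mucous cell markers limma called 15 lower with size factors, and 16 and 14 with the other scales. Their median was −2.37. A common scale moves all genes of a position the same way, so it does not account for both lists. A smaller share of 1 main cell type distally would raise the markers of all others. Of 14 cell type lists, 4 were over-represented among lower genes alone, as many as among higher genes alone. These 4 include the ionocyte and mucous cell list of the pattern itself, the only one to hold in camera with an estimated correlation (adjusted p = 0.0162). Cartilage and iridophores lost this on limma calls (Fisher's exact test, adjusted p = 0.0852 and 0.132). The leukocyte list stood at adjusted p = 0.680 in camera with an estimated correlation and at 0.0221 with the preset one. The test therefore cannot decide on this explanation. A larger share of melanophores distally and a change of expression within them cannot be told apart, since that 0 of 18 markers lay below 0 by more than 2 standard errors and 15 above, with limma log2 fold changes from −0.47 to 2.75, restates the pattern. Both stay open, as does a smaller share of 1 main cell type. A difference between the positions in mucous cells also stays open and was not tested.

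Libraries of the 3 positions deviated from their position means together, in 5 trios of 1 library each. The correlations, across 18726 genes that are not independent replicates, ran from 0.156 to 0.406 within trios and from −0.194 to 0.0473 between them. Library depth acting alike at the 3 positions would join libraries of the same rank of size factor. Of 10 links from proximal libraries 0 did so, where chance gives 2, so this form of depth found no support. The ranks of the proximal libraries ran against those of their middle and distal partners (Spearman rho = −0.70 and −0.90, n = 5 trios). Those of the middle and distal partners had rho = 0.40. Whether depth acts on the trios in another way is left open. The same fish or the same handling in a trio is a candidate explanation. The direct and the indirect match were the same for 5 of 5 proximal libraries, which has a chance of 0.00833 if the 3 matchings are independent. All 3 were chosen for high correlations among the same libraries, so their independence is not given. The same 5 trios came from 2453 genes with a mean of at least 1000 and from 8157 genes called in no comparison. These genes were read in the same libraries and are no independent check. No biological explanation was tested, and the trios were used in no comparison.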

How the results depend on the processing

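The limma fits, with the tests on recovered libraries, were chosen after seeing the data; the other alternatives were not. In the authors' deposited tables, an absolute log2 fold change of at least 1 left 3123 calls for the distal against the proximal fin, 486 for the middle against the proximal and 1914 for the distal against the middle. An adjusted p under 0.01 left 1132 for middle vs proximal, and both are stricter rules on the same genes. For that pair limma called 2614 genes, 2599 with no filter, 2634 scaled by the totals of uniquely solved genes and 2935 with positions scaled to equal totals of all genes, against 1721; the cause was not tested. All other counts of these 3 comparisons stayed within 1.5 times the first value. Leave-one-out limma fits called 9023 to 9617 genes for the distal against the proximal fin, 2064 to 2544 for the middle against the proximal and 6531 to 7127 for the distal against the middle. With a step of at least 10% of the mean 4751 monotonic genes were left, and 877 with both neighbouring comparisons past the threshold, by construction fewer.

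Of 174 list tests by Fisher's exact test 70 passed, and 48 to 65 under the alternatives. With an estimated correlation, camera of limma called far fewer lists: 2 of 29 for the distal against the proximal fin, 0 for the middle against the proximal (5 at an unadjusted p under 0.05) and 3 for the distal against the middle. With the preset correlation it called 9, 7 and 15 of the 29 lists in these 3 comparisons, so the outcome depended on the correlation used. Middle vs proximal lists past it included xanthophore (adjusted p = 2.28e-10, camera), epidermis (1.37e-08) and cell cycle members (4.43e-06). For distal vs middle they included leukocyte (5.77e-05), amino acid (2.26e-05) and appendage members (0.000696). The estimated correlation came from a fit in which the trios of libraries were not a block. No named gene reversed under a setting that tested it; the limma fits did not test the 2 *otud4* genes. Scaling by totals of uniquely solved genes moved the median log2 fold change of all genes by −0.08 at most, and scaling to equal totals by 0.07.

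For each comparison, of 100 splits of its 10 libraries, 1, the real one, gave as many limma calls. That is the smallest share this test can give, and it covers the number of calls as a whole. Every other split mixes both positions, so the test says nothing of single genes, of lists or of handling that went with position. The real values were 9352, 2332 and 7083 for the distal against the proximal, the middle against the proximal and the distal against the middle fin, and the highest others 0, 2 and 1. No paired analysis was possible because the recovered libraries carry no replicate number of the labels. The trios of libraries found from the values were not used as a block. The edgeR and DESeq2 tests planned for tables with counts per library, and fits without each replicate number, were not run; limma and its leave-one-out fits on recovered libraries took their place.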

Other observations

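Some genes peaked or dipped in the middle of the fin. *krtt1c19e*, a keratin gene, stood at 5025 ± 770.4, 21583 ± 2576 and 1985 ± 836 normalized counts (mean ± SD, n = 5) from proximal to distal, and the periostin gene *postnb* at 7319 ± 507, 15313 ± 1248 and 7378 ± 517. The fibronectin type III domain genes *fndc7a* and *fndc7b* stood at 20.4 ± 11.7, 73.2 ± 18.4 and 1.57 ± 1.25 and at 22.3 ± 10.5, 111 ± 27.2 and 3.04 ± 2.98, and *otofb* at 12.3 ± 6.75, 86.6 ± 22.2 and 2.82 ± 1.95. Lowest in the middle were *mslna*, at 151 ± 61.7, 4.31 ± 1.13 and 244 ± 51.5, and the transcription factor genes *lhx9*, at 114 ± 9.43, 60.5 ± 3.51 and 122 ± 29.0, and *pbx4*, at 708 ± 39.9, 505 ± 37.1 and 661 ± 90.1.

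A group of 4 genes varied between proximal libraries, each highest in library 2 and lowest in library 3. In libraries numbered 1 to 5 by size factor, *scpp7* stood at 115, 716, 21.3, 91.3 and 289 normalized counts, *scpp6* at 84.5, 327, 16.4, 52.5 and 143, *paplnb* at 205, 455, 22.2, 148 and 195, and *c6ast1* at 19.5, 93.3, 9.67, 33.998 and 60.6. *otud4* ENSDARG00000087953 stood at 0.945, 0, 5278, 5253 and 1823 in the 5 distal libraries, and *otud4* ENSDARG00000087337 at 0, 2.13, 562, 3959 and 507.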
